A study of Mus musculus with 6 samples.

How the data were processed

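RNA was measured in 6 A375 xenograft tumours, 3 from mice given vehicle and 3 from mice given ZLD1039 at 100 mg/kg, all on day 27. Per the labels' protocols, mRNA was purified on beads from the tumours and libraries were made with a SMARTer mRNA kit. Groups and replicate numbers were taken from the sample titles. The labels' protocols put 5 mice in each group and sequenced 3 tumours of each; they do not state outright that each tumour came from a separate mouse, so the p-values measure the spread between these tumours.

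The authors deposited, for each tumour, a list of transcript events with an FPKM value for each, per the file headers. Events of 1 locus share a locus identifier, and most loci carry an Ensembl gene identifier. The submitters' processing notes name bcl2fastq 2.17.1.14, HTSeq 0.6.1 and the mouse build mm10. The aligner, the assembler and the program that listed the events are not given in the sources used here. The positions contradict the named build: they include 3 chromosome numbers that mm10 lacks and positions past the end of mm10's annotated chromosomes. The names and lengths of the chromosomes and the unplaced contigs are those of human GRCh37, from background knowledge of that build. No human genome or annotation was used here, and positions are given as in the files.

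Events with no abundance are not listed, so an event or locus missing from a tumour's list was given the value 0. An unlisted locus need not be silent: 25 loci with a median above 10 FPKM where listed were missing from at least 1 tumour. The low values were searched for steps of single fragments, which would give the depth. Only 80 of 722 loci with a single event were listed in all 6 tumours, 4 of them below 0.5 FPKM, too few to recover it. Depth is therefore unknown, FPKM values are not counts, and no count model was used. The coordinates of skipped junctions in the column that describes each event's structure had been changed, as a spreadsheet would do, with a comma added between digits in all of them and a final 0 in all numbers over 15 digits (21610 of 23766 in vehicle tumour 1). Events were matched by the start and end columns instead.

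The value of a locus was the largest of 3 quantities: its summed start events, its summed end events and its largest event. Each is a lower bound of the abundance of the locus. This choice was made after the results of all 3 forms tried were seen. Summed start events, the first form, gave 0 changed loci of 10349 tested, the largest event 1 of 10729, and the form used here 2 of 10834. The reason for the change was that 585 to 771 listed loci per tumour had no start event, and that in 1656 to 1803 the largest event exceeded the summed starts.

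Loci and events with a mean of at least 1 FPKM in at least 1 group were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. A fold change on that scale understates the change of low values. This was the test planned before the data were examined for files without counts, with no block for replicate number. Events with the same value in every tumour of a group, often 0, carry little variance, and limma's shared variance estimate then sets the error.

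Inclusion of an exon or retention of an intron was the FPKM with the exon or intron over the sum of the FPKM with and without it, in percent. The share of a start or end site was its FPKM over the summed starts or ends of the locus. Items with a mean total of at least 1 FPKM and a total above 0 in all 6 tumours, and for the tests with a mean share over 1% and under 99%, were used. Shares were tested with limma, and mean inclusion per tumour with an exact two-sided permutation test, which cannot go below 0.1 here. Chromosomes with at least 5 tested loci were compared with all other loci by limma's camera, with a preset correlation of 0.01 and with an estimated one. The analyses of events, inclusion, sites and chromosomes were chosen after the layout of the files was seen. Earlier forms of the inclusion and start site tests used other filters, and their counts are given with the alternatives.

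The tests were run on simulated data, with 200 changed items in each of 5 runs over the real means and spreads. Where fewer items change, the adjusted threshold is stricter and a smaller share of the changes would be found. Among 10834 loci the fit found 36.4% of 2-fold, 82.0% of 4-fold and 92.0% of 8-fold changes, with 5.4 false calls of 159.4 on average. Among 82894 events it found 18.0% of 4-fold and 45.2% of 16-fold changes, and no 2-fold change. Among 13274 exons and introns it found 8.1%, 28.4% and 46.1% of differences of 20, 40 and 60 percentage points. The shares were 19.7%, 35.8% and 53.3% among 21321 start sites and 36.7%, 55.5% and 67.6% among 4610 end sites. False calls of simulated events averaged 1.8 per run. Splitting the real tumours into 3 and 3 in ways other than by treatment gave 4 to 47 events. The simulated events thus lacked part of what leads to calls in the real ones, and their shares are a guide only.

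The rule for named genes, written before the data were examined, took annotated genes past the threshold without overlap between the groups, and the smallest p-values of a direction where none passed. As applied, the loci of a direction where none passed were also limited to those with an Ensembl identifier and without overlap. The files hold 14202 Ensembl identifiers and none (0) matched the name table used here, which is for the mouse. No gene is therefore named, at most 2 identifiers are given per direction, and EZH2 and the other Polycomb subunits, the gene lists fixed beforehand and the cell type markers were not analysed here. XLOC_084825 has no Ensembl identifier and so falls outside the rule. It was named after its values were seen, as were the events given by position. How many identifiers to give per direction was settled while the rule was applied, after earlier picks had been seen.

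Alternatives were the pseudocount, filters on low values, scalings, the form of the locus value, the model's variance settings, the threshold, a block for replicate number and each tumour left out in turn. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used besides R.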

Results

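The series profiled RNA from subcutaneous tumours grown in BALB/c nude mice from A375, an established human melanoma cell line. Mice were given ZLD1039 by mouth at 100 mg/kg once a day, or vehicle alone, and the tumours were taken on day 27. ZLD1039 is an inhibitor of EZH2, the subunit of the Polycomb repressive complex that places methyl groups on histone H3 and keeps silent genes silent. Sequenced tumours numbered 3 in each group, 6 in all. The comparison asks which transcripts differ between tumours under the inhibitor and tumours under vehicle.

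Each tumour's data list transcript events with their abundance in FPKM: transcription start sites, transcript end sites, skipped and included exons, retained and spliced introns, and alternative exon ends. Vehicle tumours 1, 2 and 3 listed 126622, 122514 and 123194 distinct events in 12758, 12508 and 12689 loci. The ZLD1039 tumours listed 123840, 117347 and 125606 events in 12608, 12114 and 12589 loci. Together the tumours held 175743 events in 15234 loci, of which 87369 events (49.7%) and 10751 loci were listed in all 6. Exon skipping made up 39.8% of the events, start sites 38744 of them, intron retention 14.8%, alternative exon ends 13.0% and end sites 10.4%. None of the 20 event types took a share of the events that differed between the groups after Benjamini-Hochberg adjustment of an exact two-sided permutation test (adjusted p = 1.0 for each). That test cannot give an unadjusted p below 0.1 with 3 tumours against 3. The number of sequenced fragments is unknown, so no counting error can be given.

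The positions are human, with chromosomes numbered up to 22, although the labels name the mouse as the organism and the submitters' processing notes name the mouse build mm10. Chromosome 1 reaches position 249214145 in the files, while the last gene of chromosome 1 in the mm10 annotation ends at 195323493. The values therefore describe transcripts placed on the human genome, that is, the tumour cells of the graft, and reads of the mouse host that were placed there cannot be separated. The files pair no gene names with their identifiers, so loci are given by identifier and position only.

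Log2 FPKM values of the loci correlated between 0.948 and 0.969 for all pairs of tumours. ZLD1039 tumour 2 stood apart. It lay at 51.9 on the first principal component, which held 34.2% of the variance, while the other 5 tumours lay between -13.3 and -4.02. Its mean correlation with the others over the 10834 loci tested was 0.919, against 0.934 to 0.943 for the other 5. Along that component the vehicle tumours, from -13.3 to -12.5, also lay below ZLD1039 tumours 1 and 3, at -9.16 and -4.02. Chance places all of 1 group below all of the other in 10% of cases. The second component, with 21.6% of the variance, did not part the groups.

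**Figure D1:**
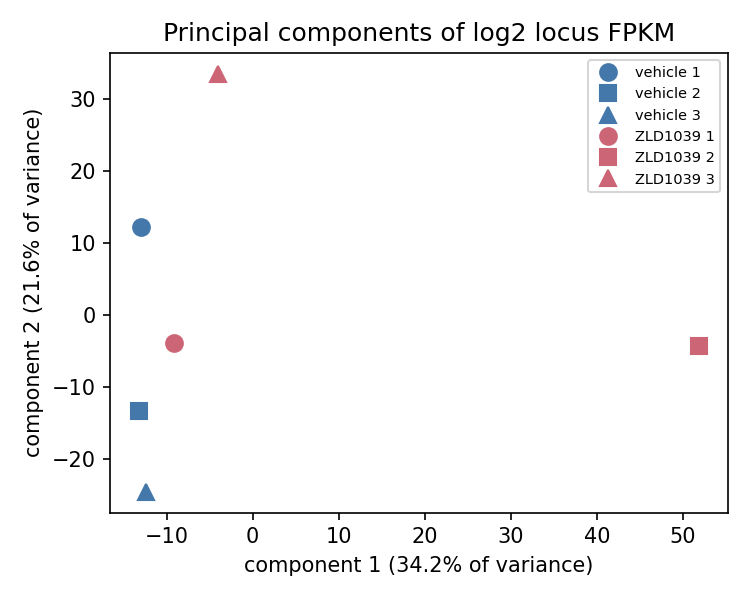
Principal components of log2 FPKM of the loci, with component 1 (34.2% of variance) on the horizontal axis and component 2 (21.6%) on the vertical axis, both in log2 units; each point is 1 tumour, vehicle in blue and ZLD1039 in red. ZLD1039 tumour 2 lies at 51.9 on component 1, apart from the other 5 tumours.

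Few loci differed in transcript abundance between the treatments. The locus ENSG00000214253 (chromosome 7, 100875373 to 100895597, minus strand) rose from 20.7 ± 3.32 FPKM in vehicle tumours to 73.1 ± 6.75 FPKM in ZLD1039 tumours (SD, n = 3). A locus on the plus strand of chromosome X (XLOC_084825, 3471258 to 3478202), for which the files carry no Ensembl identifier, was listed in every ZLD1039 tumour, at 6.75, 12.6 and 6.74 FPKM, and in no vehicle tumour. These were the 2 loci of 10834 tested that passed the threshold, both higher under ZLD1039 and none lower. Both lay at separate levels in the groups, with all 3 ZLD1039 tumours above all 3 vehicle tumours.

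For ENSG00000214253 the log2 change, on the scale of log2(FPKM + 1), was 1.78 with a standard error of 0.17 (95% interval 1.37 to 2.18, limma with Benjamini-Hochberg adjusted p = 0.048). For XLOC_084825 limma gave an adjusted p of 0.036; no fold is given against tumours in which a locus is not listed. Among loci with lower values, none passed. ENSG00000221926 (chromosome 17, 15491702 to 15587625, minus strand) measured 12.2 ± 2.09 FPKM under vehicle and 3.26 ± 1.1 FPKM under ZLD1039 (SD, n = 3), a log2 difference of -1.65 with a standard error of 0.23 (limma, adjusted p = 0.34). ENSG00000181458 (chromosome 3, 100211463 to 100293503, plus strand) measured 17.7 ± 2.82 and 7.80 ± 0.79 FPKM (SD, n = 3), a log2 difference of -1.08 with a standard error of 0.18 (limma, adjusted p = 0.58). Both were picked among loci with an Ensembl identifier and without overlap between the groups, so their separation follows from the pick.

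**Figure D2:**
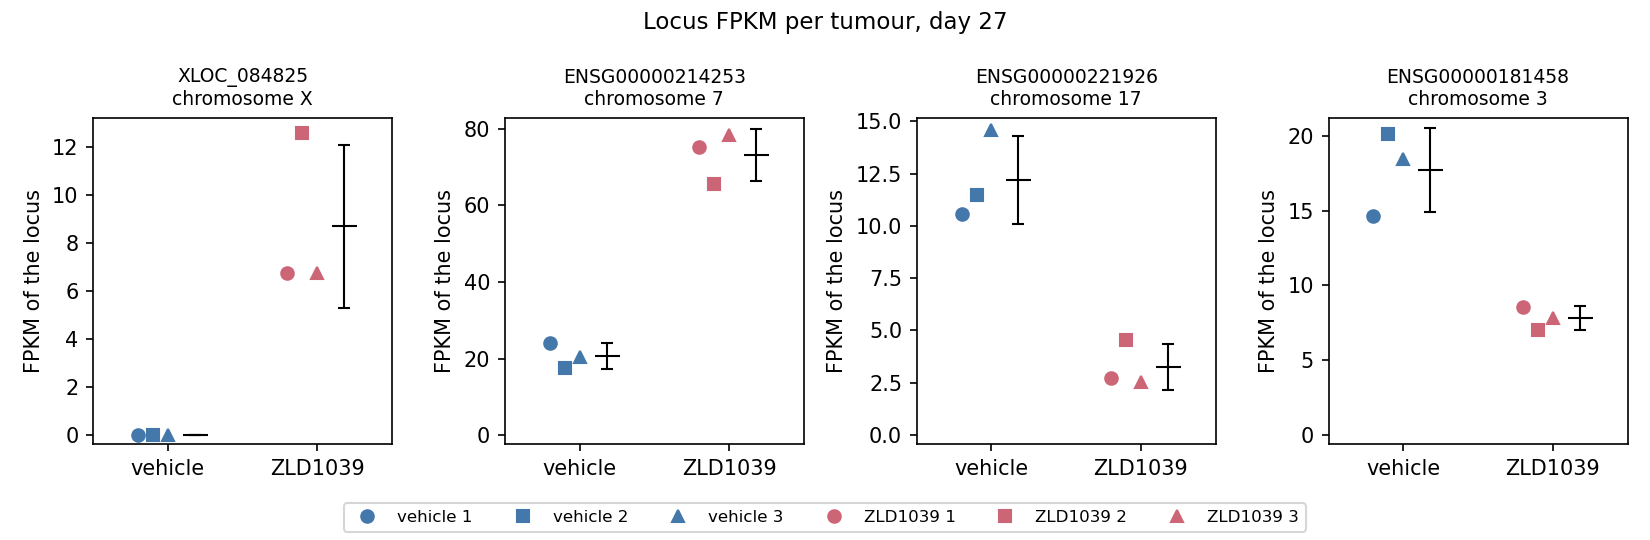
FPKM of 4 loci (vertical axes, linear, a separate scale for each locus) in the 3 vehicle tumours (blue) and the 3 ZLD1039 tumours (red), 1 point per tumour; black bars give mean ± SD, and a point at 0 is a tumour that does not list the locus. XLOC_084825 and ENSG00000214253 are higher under ZLD1039, while ENSG00000221926 and ENSG00000181458 have lower values that did not pass the test.

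Across all loci limma gave an unadjusted p under 0.05 for 535. Evenly spread p-values would give 542, and the other 9 splits of the tumours into 3 and 3 gave 291 to 703. Groups without overlap were found at 10.9% of loci, where chance gives 10%. The median standard error of a log2 change was 0.23 and the median 95% interval reached 0.53 on either side of the estimate. Neither rise kept its call when any 1 tumour was left out, although the log2 change of ENSG00000214253 stayed between 1.67 and 1.89. The count was 0 with the summed start sites as the locus value and 1, XLOC_084825, with the largest event. For ENSG00000214253 the adjusted p was 0.235 and 0.223 with these 2 forms (limma). Of the 3 forms it thus passed only with the one chosen after all results were seen. The other 9 splits of the tumours into 3 and 3 gave 0 to 2 loci. On simulated changes in these loci the same fit found 36.4% of 2-fold and 82.0% of 4-fold changes. Each of those runs held 200 changed loci and gave 159.4 calls on average, which makes the adjusted threshold easier to pass. With 2 calls it is stricter, so these shares overstate what the fit could find here if few loci changed.

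Few single transcript events differed. At 30 events in 14 loci the abundance differed between the groups, 22 of them higher and 8 lower under ZLD1039, out of 82894 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The smallest adjusted p was 0.0084. Events of the same transcript share their values, so that the 30 events hold 17 distinct sets of values. The 14 loci divided into 8 with higher and 6 with lower events.

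An intron on chromosome 20 (42087149 to 42088411, plus strand) was retained at 19.8, 18.8 and 23.1 FPKM in the ZLD1039 tumours and was not listed as retained in any vehicle tumour (limma, adjusted p = 0.0084). A transcript end on chromosome 19 (49950471 to 49950724, minus strand) was used at 25.9, 24.98 and 31.9 FPKM in the vehicle tumours and was listed in no ZLD1039 tumour (limma, adjusted p = 0.0084). A start site on chromosome 1 (6579505 to 6580121, minus strand) was used at 19.1, 24.1 and 13.4 FPKM in the vehicle tumours and listed in no ZLD1039 tumour (limma, adjusted p = 0.022). Transcripts including an exon on chromosome 7 (100887288 to 100887420), inside ENSG00000214253, stood at 9.68, 9.47 and 13.5 FPKM under vehicle. Under ZLD1039 they stood at 69.7, 54.0 and 72.0 FPKM, a log2 change of 2.48 with a standard error of 0.21 (limma, adjusted p = 0.032). These are abundances in a locus that itself rose, not inclusion in percent. Of the 30 events, 10 were unlisted in all vehicle tumours and 5 in all ZLD1039 tumours. The loci moved less than their events: in 13 of the 14 the change of the locus was less than 0.25 times the change of its event on the log2 scale, with a median of 0.068.

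An unadjusted p under 0.05 was found by limma for 3900 events. Evenly spread p-values would give 4145, and the other 9 splits of the tumours into 3 and 3 gave 2780 to 4130. None of the 30 kept its call when any 1 tumour was left out: limma called 0 events without vehicle tumour 1, 2 or 3 or ZLD1039 tumour 2, and only events outside the 30 without ZLD1039 tumour 1 (5, of which 4 higher) or ZLD1039 tumour 3 (6, all lower). The other 9 ways of splitting the 6 tumours into 3 and 3 gave 4 to 47 such events.

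Mean exon inclusion and mean intron retention differed little between the groups. Single exons that can be skipped were included at 57.4 ± 0.23% in vehicle and 57.5 ± 0.34% in ZLD1039 tumours (SD, n = 3, mean over 11888 exons), with an exact two-sided permutation p of 0.5. Runs of neighbouring exons were included at 74.9 ± 0.24% and 74.8 ± 0.73% (2616 runs, exact p = 1.0). Introns were retained at 19.98 ± 0.81% and 19.4 ± 0.73% (3757 introns, exact p = 0.5), and runs of neighbouring introns at 12.9 ± 1.65% and 12.7 ± 1.6% (652 runs, exact p = 0.6). Each of these differences lay within the spread of the tumours.

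Retention differed more between tumours of 1 group than between the groups. Introns were retained at 20.9, 19.6 and 19.5% in vehicle tumours 1, 2 and 3 and at 20.2, 18.9 and 19.0% in the ZLD1039 tumours. Skippable exons with a length that is a multiple of 3, which keep the reading frame when skipped inside a coding sequence, made up 42.8% of the 11888. Their mean inclusion exceeded that of the other exons by 2.13 ± 0.24 percentage points in vehicle and 2.13 ± 0.18 in ZLD1039 tumours (SD, n = 3, exact two-sided permutation p = 1.0). Exons of at most 50 bases were included at 45.0 ± 0.69% and 45.0 ± 0.44%, those of 51 to 200 bases at 59.0 ± 0.15% and 59.2 ± 0.38%, and longer ones at 55.3 ± 0.59% and 54.9 ± 0.41% (SD, n = 3).

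**Figure D3:**
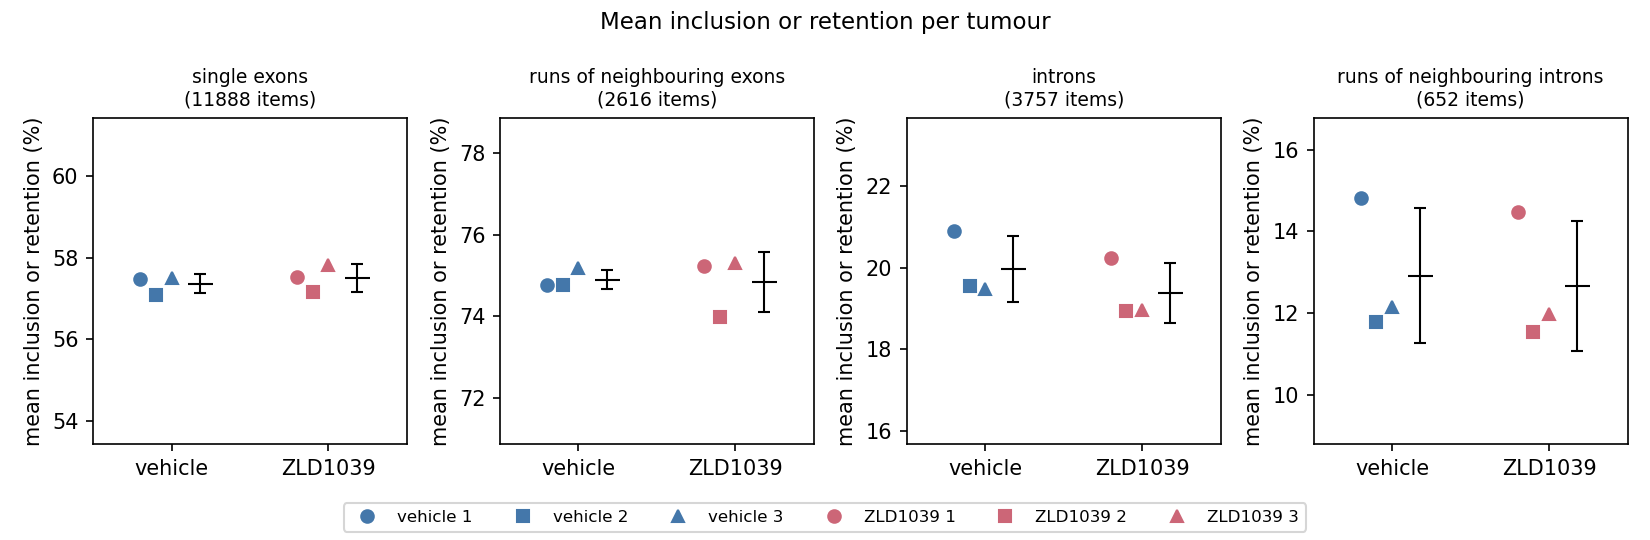
Mean inclusion of skippable exons and runs of exons, and mean retention of introns and runs of introns, in percent (vertical axes, each spanning 8 percentage points and not starting at 0), for 3 vehicle tumours (blue) and 3 ZLD1039 tumours (red); black bars give mean ± SD. The group means differ by -0.60 points for introns and by less for the other kinds, within the spread of the tumours.

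No single exon, intron or run passed the threshold among the 13274 tested (limma, smallest adjusted p = 0.72). An unadjusted p under 0.05 was found for 278, where evenly spread p-values would give 664. The other splits of the tumours into 3 and 3 gave 226 to 298, so limma's p-values for these shares were conservative. The median 95% interval of a difference reached 17.4 percentage points on either side, and a simulated difference of 40 points was found in 28.4% of cases and of 20 points in 8.1%, so smaller shifts at single exons would rarely be found.

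Most loci with several start sites kept the same leading site in all tumours. Of 7220 loci with at least 2 start sites, 4590 (63.6%) had the same leading start site in all 6 tumours, and the leading site carried 82.4 to 84.0% of the start abundance on average, by tumour. In 31 loci 1 site led in all vehicle tumours and another in all ZLD1039 tumours. The other 9 ways of splitting the 6 tumours into 3 and 3 gave 20 to 38 such loci, with a median of 26. None of 21321 start sites passed the threshold for its share of the locus (limma, smallest adjusted p = 0.34). An unadjusted p under 0.05 was found for 530, where evenly spread p-values would give 1066. The other splits gave 439 to 619, so this test was conservative. A simulated shift of 40 percentage points was found for 35.8% of start sites, and 6 of the 30 events that differed in abundance were start sites. None of 4610 end sites passed either (limma, smallest adjusted p = 0.34). For them 132 had an unadjusted p under 0.05, against 230 for evenly spread p-values and 96 to 137 in the other splits.

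Loci on chromosome 9 had lower values in the ZLD1039 group, and those on chromosome 13 higher ones, relative to all other loci. On chromosome 9 the median log2 change was -0.12 over 463 loci, and 306 of them lay below 0 (limma's camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted p = 0.0039 over 23 chromosomes). On chromosome 13 the median was 0.12 over 199 loci, with 129 above 0 (camera, adjusted p = 0.0071). With an estimated correlation between loci neither call held: the adjusted p was 0.97 for chromosome 9 and 0.18 for chromosome 13 by limma's camera. The estimated correlation was 0.157 for chromosome 9 and 0.0021 for chromosome 13. The estimate for chromosome 13 lies below the preset 0.01, so correlation between its loci cannot be what lost its call.

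The shift of chromosome 9 sat in ZLD1039 tumour 2. Its chromosome 9 loci had a median log2 deviation of -0.32 from the mean of the other 5 tumours, and 370 of 463 (79.9%) lay below 0, while the medians of the other 5 tumours lay between 0.03 and 0.10. Without that tumour the median log2 change of chromosome 9 was 0.0015 (camera, adjusted p = 0.95). Without ZLD1039 tumour 1 the call of chromosome 13 was lost (camera, adjusted p = 0.097), with a median of 0.14. It held without any other single tumour (camera with the preset correlation, adjusted p at most 0.0485). The shift of chromosome 13 was not confined to 1 tumour. Its median deviations were 0.06, 0.12 and 0.06 in ZLD1039 tumours 1, 2 and 3, and -0.04, -0.09 and -0.05 in the vehicle tumours. Each of the other 9 splits of the tumours into 3 and 3 also called 1 to 3 chromosomes by camera with the preset correlation. Calls of this kind are therefore not particular to the treatment split.

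**Figure D4:**
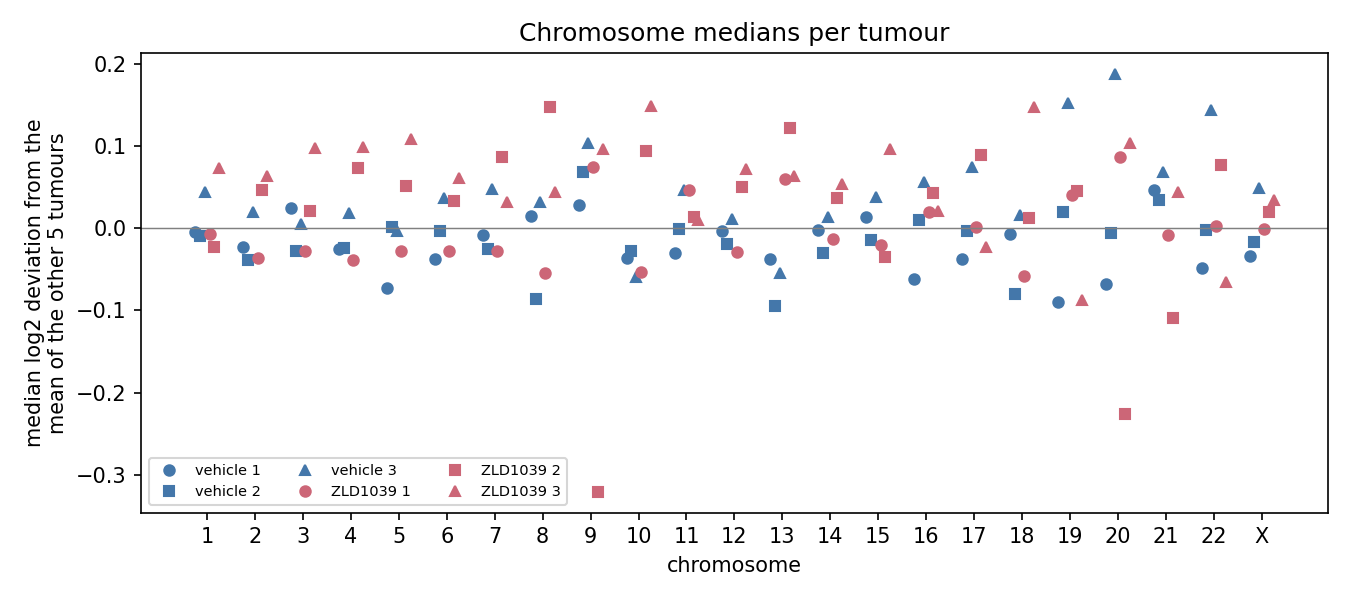
Median log2 deviation of each tumour's loci from the mean of the other 5 tumours (vertical axis), by chromosome (horizontal axis); 1 point per tumour, vehicle in blue and ZLD1039 in red. ZLD1039 tumour 2 lies at -0.32 on chromosome 9 and -0.23 on chromosome 20, the lowest points in the plot.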

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

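All alternatives for events, inclusion, sites and chromosomes, and for loci the scalings, weights, trend, locus forms and the filter of at least 1 FPKM in at least 3 tumours, were chosen after seeing the data. The 2 changed loci became 0 without a filter on low values and with summed start events. They became 1 with a pseudocount of 0.1, median-of-ratios scaling, quantile normalization, the 20 most abundant and the mitochondrial loci left out, the largest event as the locus value, and no mean-variance trend. With 1 tumour left out the count was 0 to 1 and held neither of the 2: the 1 locus, called without vehicle tumour 1, was another one and lower. Without the filter 15234 loci were tested. The cause was not tested. The log2 change kept its sign at all 4 named loci in each of 19 alternatives. The groups did not overlap at these loci. Leaving out a tumour or changing the threshold, the block or the variance settings could therefore not reverse the sign. With 1 tumour left out the log2 change was 1.67 to 1.89 for ENSG00000214253. No size is given for XLOC_084825, since the pseudocount sets it where no vehicle tumour lists the locus. The call was lost in 15 of the 19 alternatives for ENSG00000214253 and 9 for XLOC_084825.

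The 30 changed events became 3 without a filter, 55 at a threshold of 0.10, and 60 without the trend. With a pseudocount of 0.1 the count was 20, of which 14 were among the 30. With 1 tumour left out it was 0 to 6, none of them among the 30. For exons and introns the count of 0 became 3 on a log2 ratio scale, 15 without the trend and 1 when the files' approximate event kinds were added with a minimum in every tumour, an earlier form of that test. For start sites it became 1 and 11, and for end sites 2 and 7, on the ratio scale and without the trend. It remained 0 in the other settings tried, an earlier form of the start site test included. The 2 chromosomes became 0 with an estimated correlation and 1 to 2 with 1 tumour left out. The cause was not tested. All differences in mean inclusion moved by less than 1 pooled SD of the groups, and those of single exons, runs of exons and runs of introns changed sign in some settings.

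The replicate numbers 1 to 3 are shared by the groups. Deviations of same-numbered tumours correlated at -0.032, 0.020 and -0.061, and no tumour correlated best with its own number, so the numbers were not taken as pairs. With a replicate block limma called 0 loci, 0 events and 0 exons, introns, start or end sites. Mean intron retention was highest in tumour 1 of both groups, and the same-numbered differences were -0.68, -0.61 and -0.50 points. They were also of 1 sign for runs of introns (-0.33, -0.27 and -0.19) and single exons (0.06, 0.07 and 0.32), and of mixed sign for runs of exons. This is a hint from the data only, for which a paired exact test cannot go below 0.25.

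The planned edgeR, DESeq2 and voom tests, the counts-per-million filter and the removal of haemoglobin genes were not run, because the files hold FPKM without gene names. The gene list and marker tests were not run for the same reason. Unknown depth leaves low values without an error of their own.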

Other observations

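Of the tests in this part, those of tumours split in other ways, of the windows of neighbouring loci and of the tumour that carries the chromosome 9 shift were chosen after the result was seen, as was the look at choices with and without ZLD1039 tumour 2. The others were set down before their values were known, though after the patterns that led to them.

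Chromosome 9 was lower along its whole length in ZLD1039 tumour 2. All 14 windows of 10 Mb with at least 10 loci had a median deviation from the other 5 tumours below 0, from -0.40 to -0.03 on the log2 scale, whereas 38.2% of all 285 windows did in that tumour and at most 35.7% of the chromosome 9 windows in any other tumour. The pattern was not particular to chromosome 9: all 7 windows of chromosome 20 lay below 0 in the same tumour, from -0.48 to -0.15, and its lowest window, at -0.48, lay on chromosome 1 (110 to 120 Mb). The shift of the group rests on this tumour, since the median without it was 0.0015 and at most -0.096 without any other single tumour. A trend with gene density argues poorly for it: after removal of each tumour's trend the median stayed at -0.30. A lower copy number of chromosome 9 in that tumour is a candidate explanation, as a hypothesis. It predicts a like shift at all levels of abundance. The medians were -0.35, -0.37 and -0.23 in 3 equal parts of the loci by FPKM, from the lowest to the highest. On the scale of log2(FPKM + 1), which understates changes of low values, a like shift would look smallest in the lowest part. The shift was smallest in the highest part instead, so these values do not bear out that prediction. DNA was not examined, a change in regulation along the chromosome stays open, and treatment cannot be tied to a shift seen in 1 of 3 treated tumours.

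ZLD1039 tumour 2 also stood apart away from chromosome 9. Fewer sequenced fragments would blur mainly low values, but over loci of at least 20 FPKM its mean correlation with the others was still 4.06 SD below that of the other 5 tumours. Over loci of 1 to 5 FPKM it lay 6.05 SD below, at 0.377 against a mean of 0.503, and its list is the shortest. The bound set beforehand would have excluded fewer fragments as the cause. Depth is unknown, however, and noise from fewer fragments can also reach loci of at least 20 FPKM, so this explanation stays open. Without chromosomes 9 and 20 it lay 5.72 SD below, so a difference in these chromosomes is not the whole cause. Its window medians spread 1.35 times as widely as after shuffling the loci, against 1.19 to 1.30 in the other tumours. The shuffled spread that this ratio divides by was also the widest in it, at 0.1131 against 0.0617 to 0.0834. The ratio alone therefore cannot decide whether neighbouring loci shift together more in it across all chromosomes. On chromosomes 9 and 20 they did, since all windows tested there lay below 0. Degraded RNA was tested through locus span, where its rank correlation across loci was -0.141, and another tumour reached 0.215. The bound set beforehand would have excluded degradation, but span includes introns and is a poor measure of transcript length, so degradation stays open, as does a different share of mouse host tissue.

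The 30 events that passed the threshold lay mostly in loci whose own change was small beside that of the event. A candidate explanation is that the abundance of 1 transcript was reassigned to another of the same locus, by the cells or by the estimation of transcript abundance. The median ratio of the locus change to the event change was 0.068, and in 9 of the 14 loci (64.3%) another event moved at least 2-fold the other way. The share was 24.4% among the 2540 loci with 2 or more tested events of which 1 moved 2-fold, but that reference does not match the 14 loci. Their events were picked for larger changes, which by itself favours a low ratio and opposite events, so the contrast is no support for reassignment. Both readings predict these values, and the files give nothing to tell a change in splicing from a change in how fragments were assigned.

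An inhibitor of a repressive complex might raise loci that were silent before. In all 3 ZLD1039 tumours and no vehicle tumour 27 loci were listed, and 38 in the reverse direction. The 20 ways of choosing 3 of the 6 tumours gave a median of 26 and a highest value of 41, and 10 gave at least 27. The comparison is uneven, since ZLD1039 tumour 2 has the shortest list: the 10 choices that include it gave 14 to 27. All choices at 30 or more leave it out. The ZLD1039 group is among those 10 and shared their highest value, 27, with another choice, but 10 choices are too few to decide. Whether derepression raised silent loci therefore stays open. The lists also leave out what was not detected, and unlisted loci need not be silent.

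With 3 tumours in each group there are 10 splits into 3 and 3, too few for a share under 0.05. The treatment split gave 2 loci and the highest other split 2, and 3 splits gave at least 2. It gave 30 events and the highest other split 47, with 3 splits at 30 or more. It gave 2 chromosomes and the highest other split 3, with 8 splits at 2 or more. For exons and introns, start sites and end sites all 10 splits gave 0.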
